A study of Homo sapiens with 2 samples.

How the data were processed

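Single-cell RNA sequencing was carried out on astrocyte progenitor cells derived from H7, a human embryonic stem cell line, with 1 library at day 160 and 1 library at day 220 of differentiation. Per the labels, the cultures received the cytokine LIF and the growth factors BMP4 and FGF1 in sequence, the cells were dissociated with the enzyme mixture Accutase, and 3 separate differentiations were combined before loading on a 10x Genomics Chromium 3′ kit. No label separates the 3 differentiations within a library, so each library was 1 sample and there was no replicate of either time point. Libraries were grouped by the time-point label. The protocol text of the day 220 library repeats the earlier day, while its title and time-point label both give day 220. The names under which the 2 libraries were deposited differ in 1 prefix whose meaning is not given in the sources used here, so a difference between the cultures other than time remains possible.

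The deposited values were raw UMI counts per gene and barcode, each UMI standing for 1 captured RNA molecule, and the authors had made these counts with Cell Ranger 7.0.1, per the file headers. Cell Ranger 7, Seurat 4 and the genome build hg38 are named in the submitters' processing notes. Whether reads in introns were counted, whether the counting used strand, the annotation release, the settings for calling cells and any filter on barcodes are not given in the sources used here. Reads of overlapping genes and of antisense transcripts such as PTCHD1-AS and DLX6-AS1 are therefore uncertain, as are counts split between near-identical genes such as HLA-DRB1 and its paralogs. Gene coordinates and intron lengths were taken from GENCODE release 29 on GRCh38, matched by Ensembl gene identifier. Intron length was the span of a gene not covered by any of its annotated exons. Of the 10163 genes counted in the main comparison, 10135 had an intron length.

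Barcodes with 1000 or more detected genes and at most 15% of UMIs from mitochondrially encoded genes passed. Scrublet, run in scanpy 1.11.5 on each library with an expected rate of 0.06, marked doublets at its automatic threshold, and these were left out. Of 13018 deposited barcodes at day 160, 9972 passed and 525 of these were left out as doublets, which left 9447 cells with 116776042 UMIs. Of 676 barcodes at day 220, 524 passed and 6 were left out, which left 518 cells with 25614704 UMIs. At day 160, 2924 barcodes were over the mitochondrial limit and 620 were under the gene limit, against 105 and 90 at day 220. A limit of 3 UMIs for a gene with no count corresponded to 0.0257 CPM (counts per 10⁶) at day 160 and 0.117 CPM at day 220.

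Counts were summed over the kept cells of a library and scaled to CPM, and the ratio of the libraries was log2 of day 220 CPM + 1 over day 160 CPM + 1. Genes with 10 CPM or more in at least 1 library were counted, by whether they lay at least 2-fold higher or lower. With 1 library per time point no test was possible and no p-value was computed. CPM values carry exact Poisson intervals, ratios carry exact conditional binomial intervals of the CPM ratio without a pseudocount, and shares carry exact Clopper-Pearson intervals, all at 95% and all covering counting error only. Where 0 cells had a UMI, the limit given is 3 cells of the total, and it holds for cells with a UMI at that depth, not for cells that express the gene. They say nothing of the spread between cultures, and cells were not treated as replicates. Fold differences in the text refer to these CPM ratios.

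Gene lists for cell types, pathways, regional identity, 6 glioblastoma cell states and 3 glioblastoma subtypes were written from general knowledge of published signatures and fixed before the data were examined, as were the filters, the comparisons and all alternatives other than those named below as added. A list was given a median log2 ratio where at least 5 members reached 5 CPM in at least 1 library, which held for 31 of 39 lists. Each median was placed as a percentile among 10000 random lists of the same size matched on mean expression in 20 bins, as a description of these libraries. The genes named are the 12 highest and 12 lowest log2 ratios among genes with 50 CPM or more in at least 1 library, leaving out mitochondrially encoded genes, ribosomal protein genes, clone-named and LINC transcripts and sex-linked identity genes; the 4 members of each list with the largest absolute ratio among those with 20 CPM or more; the 5 leading genes of each cluster; and a fixed set of glial, progenitor, neuronal and cycling genes. Not all genes that meet this rule are named in the text, and genes named outside it are said to be so.

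Each library was clustered alone after scaling to 10000 counts per cell, log transformation, selection of 2000 variable genes, 30 principal components, 15 neighbours and Leiden clustering at resolution 0.5. Clusters are numbered by size within their library. Leading genes were ranked by the fold of CPM + 10 against all other cells of the library, among genes detected in at least 25% of the cluster. A cluster was called after a cell type, as X-like, where at least 3 markers of that type were 2-fold or more above the rest and detected in at least 25% of the cluster, with more such markers than for any other type and no larger number of another type's markers among its top 10 genes. A class was compared between libraries where both held at least 50 cells of it. For shares of cells with a UMI, each cell was thinned to 5000 UMIs. This left out 692 kept cells at day 160 and 30 at day 220. For the glioblastoma lists, the score of a cluster was the mean over list members of log2 of CPM + 10, minus the mean of that value over the clusters of the same library.

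Alternatives covered the cell filter, doublets, scaling, pseudocount, expression filter, cycling clusters, thinning depth, clustering resolution, joint clustering and list membership. After the data were seen, a mitochondrial limit of 25% was added, together with 3 uses of intron length: centring each log2 ratio on the median of genes in the same of 20 bins of intron length, restriction to genes with 10000 or fewer intron bases, and joint clustering on those genes. The comparison was tested on simulated data drawn from the day 160 means, at the UMI totals of both libraries. It covered genes with 10 CPM or more at day 160 and an intron length, which leaves out such genes as PTCHD1-AS and LRP1B. Of the 8581 genes simulated, 200 were changed. These were 44 genes 4-fold lower, 48 genes 3-fold lower, 50 genes 3-fold higher and 58 genes 4-fold higher. All were recovered without a trend, and 0 unchanged genes lay past 2-fold. With a simulated intron-length trend 42, 38, 48 and 54 of them were recovered in that order, and 271 unchanged genes lay past 2-fold. Once that trend was centred, 44, 48, 49 and 58 were recovered and 3 unchanged genes lay past 2-fold. The simulated trend was a straight line on the logarithm of intron length with counting error only. Its Spearman's rho was 0.99 among unchanged genes, against 0.64 in the data, where the rise was steepest at long introns. The simulation therefore does not show how well centring removes the trend of the data. The ratio intervals covered the true ratio of 94.9% of the simulated genes without a trend. Calculations used Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and igraph 0.11.9.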

Results

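The data were 2 single-cell RNA libraries of astrocyte progenitors made from the H7 embryonic stem cell line, 1 from day 160 and 1 from day 220 of differentiation. The day 160 library had 9447 kept cells with a median of 10077 UMIs and 3210 detected genes. The day 220 library had 518 kept cells with a median of 46079.5 UMIs and 7751.5 detected genes, so it held fewer cells at a greater depth per cell. Mitochondrially encoded genes took 11.7% of the UMIs of kept cells at day 160 and 8.82% at day 220, and ribosomal protein genes took 15.1% and 12.3%. Each library pooled 3 differentiations and neither time point had a replicate, so the differences given here are between these 2 libraries, with intervals for counting error only. The series asks which progenitor subtypes are present at the 2 times and how they relate to the subtypes of glioblastoma, a malignant brain tumour.

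Between day 160 and day 220, the day 220 library had lower levels of genes of cell division and of neuronal precursors and of HOXB2, HOXB6 and HOXB8, and higher levels of most listed targets of fibroblast growth factor and ERK signalling. CRABP1, which encodes a retinoic acid-binding protein, was close to 0 at day 220. CRABP1 (ENSG00000166426, chromosome 15, 78340324 to 78348230 on GRCh38) had 594 CPM (590 to 599) at day 160 and 0.43 CPM (0.21 to 0.77) at day 220, a level 1383-fold lower (773 to 2772) and resting on 11 UMIs. GFAP, the intermediate filament gene of astrocytes, had 549 CPM (545 to 553) at day 160 and 136 CPM (131 to 140) at day 220, 4.05-fold lower (3.91 to 4.19). S100B, a calcium-binding gene of glia, was 3.30-fold higher (3.23 to 3.37) at 566 CPM (556 to 575) against 171 CPM (169 to 174).

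The lowest ratios also held NNAT, an imprinted gene of the developing brain, at 51.7 CPM against 0.04 CPM from 1 UMI, 1325-fold lower (238 to 52350). CALB2, the calretinin gene of interneurons, was 13.7-fold lower (12.1 to 15.4) and the Notch target HES5 was 8.67-fold lower (8.13 to 9.25). The acute-phase gene SERPINA3, the mitotic gene UBE2C and the patterning gene HOXB2 were 7.55-fold (6.54 to 8.77), 6.75-fold (6.27 to 7.28) and 8.04-fold (7.07 to 9.18) lower. RASD1, SOCS2, CDO1 and IQGAP2 were among them too, at log2 ratios of -3.57, -2.89, -2.90 and -2.89.

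The 12 highest ratios were PTCHD1-AS, LRP1B, DLG2, FAM155A, ALK, FRMD5, KCNH7, CACNB2, RGS6, STXBP5L, DEC1 and SNTG1, with log2 ratios from 8.30 for PTCHD1-AS to 5.61 for SNTG1. PTCHD1-AS (ENSG00000233067, chromosome X, 22259797 to 23293146), an antisense transcript, had 0.27 CPM (0.19 to 0.39) at day 160 and 401 CPM (393 to 409) at day 220. LRP1B (chromosome 2, 140231423 to 142131701), of the low-density lipoprotein receptor family, had 2.27 CPM and 496 CPM, 219-fold higher (194 to 248). DLG2, a scaffold gene of the synapse, had 7.16 CPM and 803 CPM, and the receptor tyrosine kinase gene ALK had 2.31 CPM and 252 CPM. Each of these genes has long introns: 1032215 annotated intron bases in PTCHD1-AS, 1883239 in LRP1B, 2156202 in DLG2, 721431 in ALK and 317819 in FRMD5, the shortest of the 12. After centring on intron length their log2 ratios were lower, from 5.76 for PTCHD1-AS to 3.07 for SNTG1.

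Of 10163 genes counted, 2323 were at least 2-fold higher at day 220 and 519 at least 2-fold lower, so 81.7% of the genes past 2-fold were higher. The ratio followed intron length (Spearman's rho across genes 0.64, genes not being independent). Among 528 genes with over 300000 intron bases the median log2 ratio was 2.57 and 88.6% were at least 2-fold higher, and among 1722 genes with 100000 to 300000 bases these were 1.24 and 59.5%. Among 1868 genes with 1000 to 10000 bases the median was -0.35 and 3.3% were 2-fold higher. After centring on genes of like intron length, an alternative chosen after the data were seen, 1027 genes were at least 2-fold higher and 776 lower, a share of 57.0% higher. Without an expression filter 4055 genes were higher and 716 lower, and among genes of 50 CPM or more 1008 were higher and 218 lower. The median of all counted genes was 0.14 as measured and 0.04 with CPM taken without mitochondrially encoded and ribosomal protein genes.

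**Figure D1:**
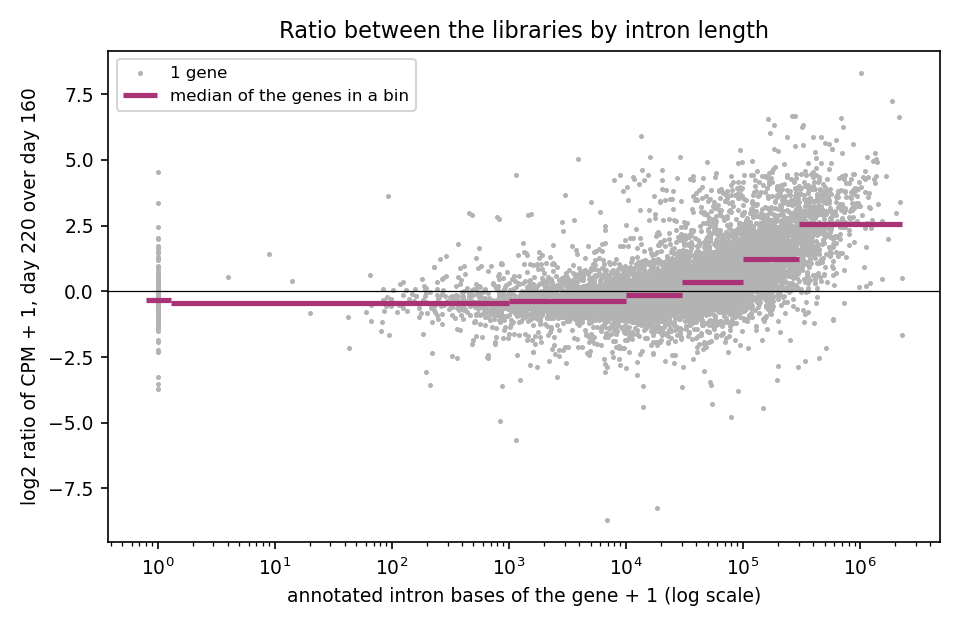
Each point is 1 of the counted genes, with its annotated intron bases + 1 on a log scale against the log2 ratio of CPM + 1, day 220 over day 160, and each bar is the median of the genes in a bin. The bar medians go from -0.33 for genes without introns to 2.57 for genes with over 300000 intron bases.

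After that centring, genes with short introns were among the highest ratios, here named after their values were seen unless a list below holds them. PTGDS, which encodes prostaglandin D2 synthase (chromosome 9, 136975092 to 136981742), had 10.1 CPM (9.49 to 10.7) at day 160 and 366 CPM (358 to 373) at day 220, 36.4-fold higher (34.2 to 38.7). OLIG1, a transcription factor gene of the oligodendrocyte lineage (ENSG00000184221, chromosome 21, 33070144 to 33072420), was 26.8-fold higher (24.8 to 28.9), at 6.79 CPM (6.33 to 7.28) and 182 CPM (177 to 187). The log2 ratios after centring were 5.37 for PTGDS and 4.91 for OLIG1. CRABP1, NNAT, CALB2, RASD1 and IQGAP2 stayed among the 12 lowest, with CRABP1 at -8.40 and IQGAP2 at -4.46.

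Genes of cell division were lower as a group. All 16 cycling genes were measured, 15 were at least 2-fold lower, 0 were 2-fold higher, and the median log2 ratio was -1.95 (-2.29 to -1.44, an interval over the members) at percentile 0.0 of the random lists. CDK1, the kinase that drives entry into mitosis, was 6.63-fold lower (6.09 to 7.24), CCNA2 5.54-fold lower (4.84 to 6.35) and BIRC5 5.11-fold lower (4.65 to 5.62). MKI67 was 3.95-fold lower (3.67 to 4.26) and TOP2A had a log2 ratio of -1.98. The list stayed at -1.84 after centring on intron length.

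Neuronal precursor genes were also lower, with 8 of 10 measured members at least 2-fold lower, 0 higher and a median of -1.28, which was -0.95 with 5 lower after centring. The forebrain interneuron gene DLX2 was 3.62-fold lower (3.50 to 3.74). HES6 and DLL3 had log2 ratios of -1.44 and -1.61. Neuron genes went both ways, with 3 of 13 higher, 5 lower and a median of -0.27, or -0.73 after centring. ELAVL4, an RNA-binding gene of neurons, was 48.3-fold lower (31.3 to 79.2), TUBB3 was 3.26-fold lower (3.20 to 3.33) and STMN2 had 11.3 CPM and 0.04 CPM, the latter from 1 UMI, 289-fold lower (51.7 to 11410). GAD1, the gene of the enzyme that makes the transmitter GABA, was 12.4-fold higher (11.6 to 13.3). SYT1 had a log2 ratio of 2.06 that turned to -0.48 after centring on intron length. DCX was 2.21-fold lower (2.14 to 2.30), and after centring DCX and ELAVL4 were at -2.16 and -5.73.

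The 5 measured genes of midbrain, hindbrain and spinal identity were each at least 2-fold lower, with a median of -2.81 (percentile 0.0), or -2.45 after centring. Across the alternatives the median of this short list ranged from -3.57 to -0.08, the last with no expression filter. HOXB6 was 9.98-fold lower (8.26 to 12.2), HOXB8 9.45-fold lower (7.36 to 12.3) and ZIC1 4.98-fold lower (4.25 to 5.87), with a log2 ratio of -3.17 after centring. Within astrocyte-like cells these genes were low at both times and went both ways. There HOXB2 was 2.19-fold lower (1.55 to 3.18) and HOXB6 had a ratio of 0.83 (0.46 to 1.40). HOXB8 was 2.83-fold higher (1.73 to 4.57), on 47 and 30 UMIs. ZIC1 was 1.72-fold higher (1.36 to 2.17), with a log2 ratio of -0.25 after centring. Of 9 forebrain genes 3 were at least 2-fold lower and 0 higher, with a median of -0.99 (-1.63 to 0.51 over members, percentile 0.0), PAX6 at -1.63 and DLX1 at -1.12, and 2 were lower after centring with a median of -0.66.

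The astrocyte and radial glia lists held genes in both directions. Of 14 astrocyte genes 3 were at least 2-fold higher and 3 lower, with a median of -0.34 and a percentile of 6.4, or -0.58 after centring. Besides GFAP and S100B, the lipid carrier gene APOE was 7.83-fold higher (7.48 to 8.20) at 196 CPM and the receptor gene FGFR3 had a log2 ratio of -1.73. The water channel gene AQP4 was low in both libraries, at 5.10 CPM (4.70 to 5.53) and 2.11 CPM (1.58 to 2.75). The glutamate transporter gene SLC1A3 had 294 CPM and 320 CPM (313 to 327), 1.09-fold higher (1.06 to 1.12). Of 18 radial glia genes 2 were higher and 6 lower, with a median of -0.08, or -0.51 with 8 lower after centring. Among them TNC, a matrix gene of outer radial glia, was 5.26-fold higher (5.13 to 5.40), PTPRZ1 3.79-fold higher (3.72 to 3.85) and HOPX 3.74-fold lower (3.58 to 3.90). NES and VIM, intermediate filament genes of progenitors, were 1.63-fold (1.60 to 1.66) and 1.09-fold (1.08 to 1.09) higher, and SOX2 and SOX9 were 1.98-fold (1.94 to 2.02) and 1.47-fold (1.43 to 1.52) lower. CD44, PDGFRA and EGFR had log2 ratios of -0.29, -0.19 and 0.79. After centring on intron length PTPRZ1 was at 0.63, TNC at 1.73 and CD44 at -0.94, while EGFR and SLC1A3 turned to -0.50 and -0.49. CHI3L1 was low in both libraries, with 0.44 CPM (0.33 to 0.57) and 1.33 CPM (0.92 to 1.85).

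Genes induced by fibroblast growth factor and ERK signalling were higher as a group. Of 13 measured members 9 were at least 2-fold higher and 0 lower, and the median was 1.48 (0.47 to 2.60, percentile 99.9), or 1.83 after centring on intron length. SPRY1, a feedback inhibitor of the pathway, was 14.6-fold higher (13.4 to 15.9), and SPRED2 9.86-fold (9.05 to 10.8). The transcription factor gene ETV5 and SPRED1 had log2 ratios of 2.60 and 2.17. Of 12 genes of the p53 response and senescence 4 were higher and 0 lower, with a median of 0.79 (percentile 97.0). CDKN2A, which encodes the cell-cycle inhibitors p16 and ARF, was 4.70-fold higher (4.52 to 4.89) and its neighbour CDKN2B 3.84-fold higher (3.43 to 4.30), while SESN1 and TNFRSF10B had log2 ratios of 1.47 and 1.08. Of 14 extracellular matrix genes 6 were higher and 1 lower, with a median of 0.74 (percentile 98.0), and LAMB1 was 5.10-fold (4.74 to 5.48), LAMC1 4.86-fold (4.63 to 5.10) and FBN1 7.12-fold (6.21 to 8.17) higher. After centring these were at log2 ratios of 1.64, 1.22 and 0.91, SESN1 was at 0.81, SPRED2 at 2.10 and SPRED1 at 1.51, and 4 matrix genes were higher and 2 lower.

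Several response lists had medians below 0. Of 13 immediate early and dissociation genes, which are induced within minutes of a stimulus or of tissue handling, 6 were at least 2-fold lower and 0 higher, with a median of -0.91 (percentile 0.0) and IER2 3.60-fold lower (3.46 to 3.75). Of 15 interferon response genes 6 were lower and 0 higher, with a median of -0.62 (percentile 0.1), BST2 at -1.85 and B2M 2.03-fold lower (2.01 to 2.05). Of 16 cholesterol synthesis genes 3 were lower and 0 higher, with a median of -0.65 (percentile 0.0), MSMO1 at -1.26 and HMGCS1 2.17-fold lower (2.09 to 2.25). Of 10 reactive astrocyte genes 3 were lower and 1 higher, with a median of -0.59 (percentile 1.0) and the adhesion gene VCAM1 5.49-fold lower (4.96 to 6.10). The interferon and reactive astrocyte medians were not below 0 in every class. They were 0.33 and 0.70 in precursor-like cells, or 0.55 and 0.11 after centring. The LIF and STAT3 list had a median of -0.43 with 2 of 10 lower, SOCS3 at -1.23 and JUNB at -0.91, and turned to 0.10 with cells thinned to 5000 UMIs. The BMP list had a median of -0.64 with 2 of 5 lower and ID2 at -0.64, and the Notch list -0.42 with 4 of 11 lower, 1 higher, HES4 at -1.66 and NOTCH2 at 1.47. After centring on intron length NOTCH2 was at 0.18 and 0 Notch members were 2-fold higher. The centred medians were -0.69 for immediate early genes with 3 of 13 lower, -0.50 for interferon with 4 of 15 lower, -0.49 for cholesterol synthesis and -0.91 for reactive astrocyte genes, at percentiles from 0.1 to 1.3. The BMP and LIF lists were at -0.32 and -0.19 after centring, with 1 LIF member lower, the latter at percentile 22.8, and neither stood apart from the random lists.

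Hypoxia and glycolysis genes had a median of -0.52, with 3 of 13 higher and 2 lower (1 lower after centring), P4HA1 at 1.33 (0.68 after centring) and LDHA at -1.03. The unfolded protein response list had a median of -0.26 that became 0.05 after centring, with 0 of 12 members past 2-fold in either direction. The glutamate list had a median of 0.00 as rounded, or -0.30 after centring, with 1 of 10 higher. The oligodendrocyte lineage list had a median of 0.98 with 3 of 6 higher and 0 lower, or 0.43 with 2 higher after centring, among them OLIG1, while OLIG2 had 0.79 CPM (0.64 to 0.97) and 5.47 CPM (4.60 to 6.45), and MBP a log2 ratio of 1.55, or 0.26 after centring. The mesenchymal list had a median of 0.83 with 2 of 5 higher (1 after centring) and COL1A1 1.80-fold higher (1.71 to 1.90). Too few members reached 5 CPM for a median in the muscle list with 4, ependymal 3, choroid plexus 2, neural crest 2, pluripotent 1, metallothionein 4, endothelial 0 and microglia 0. DPPA4, the pluripotent member, had 24.1 CPM and 23.1 CPM.

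**Figure D2:**
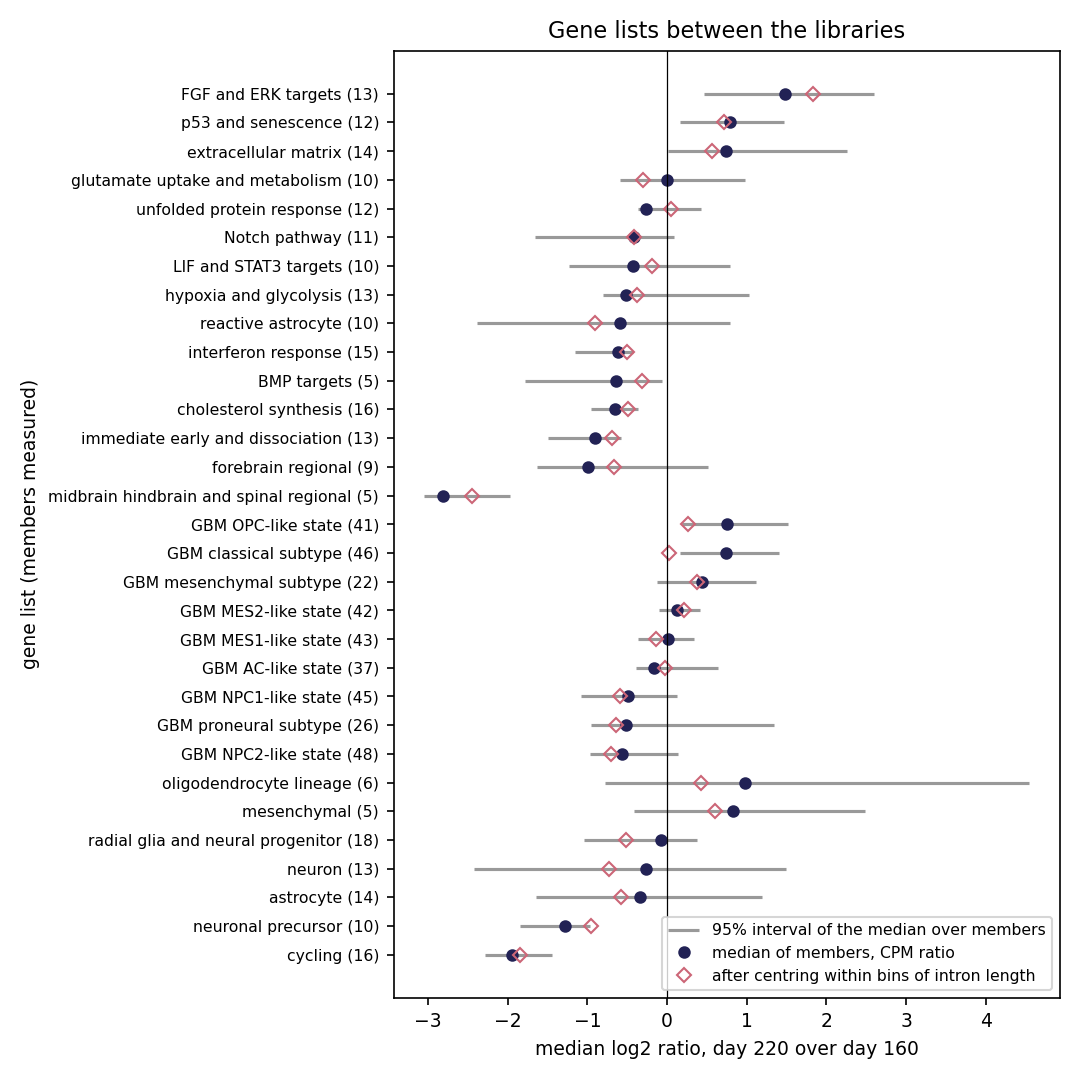
Filled circles are the median log2 ratio, day 220 over day 160, of the measured members of each list, grey lines are the 95% interval of that median over members (the whole range for lists of 5), and open diamonds are the medians after centring on intron length. The FGF and ERK list lies highest at 1.48 and the midbrain, hindbrain and spinal list lowest at -2.81.

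Fewer cells carried division transcripts at day 220. At 5000 UMIs per cell, 1194 of 8755 cells (13.6%, 12.9 to 14.4) had a UMI of both MKI67 and TOP2A at day 160 and 19 of 488 (3.89%, 2.36 to 6.01) at day 220, with 16.6% and 5.60% before thinning. In astrocyte-like cells, which were not in a cycling cluster, the share was 0 of 2028 at day 160 (a limit of 0.15%) and 0 of 119 at day 220 (a limit of 2.52%), at median depths of 14399.5 and 63316.5 UMIs before thinning. Dividing cells were set apart in cycling-like clusters, so these shares do not show whether astrocyte-like cells divide. Over all kept cells the shares were 7.42% and 1.78% at 2000 UMIs and 23.9% and 4.2% at 10000, where 4682 day 160 cells and 42 day 220 cells were too shallow and left out. The ratio of the shares was 4.17 at 2000 UMIs, 3.51 at 5000 and 5.68 at 10000.

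CRABP1 was found in 26.5% of thinned cells (25.6 to 27.5) at day 160 and in 0 of 488 at day 220, which allows a share of up to 0.61% with a UMI at that depth. Before thinning these were 31.3% and 1.35%. In the astrocyte-like cluster of day 160, 3.94% of thinned cells had CRABP1. HOXB6 was found in 14.6% (13.9 to 15.4) and 0.82% (0.22 to 2.09), or 19.7% and 8.30% before thinning, with 0.84% in astrocyte-like cells at day 160.

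OLIG1 was found in 2.56% of thinned cells (2.24 to 2.91) at day 160 and in 24.4% (20.6 to 28.5) at day 220, or 3.96% and 49.4% before thinning. In neuron-like cells it was found in 0 of 43 at day 160 and in 0 of 21 at day 220, at median depths of 5558.5 and 18690.5 UMIs. PTGDS was found in 3.50% (3.12 to 3.90) and 44.3% (39.8 to 48.8), or 6.30% and 75.5% before thinning, with 0 of 43 and 1 of 21 in neuron-like cells. APOE was found in 4.89% (4.45 to 5.36) and 28.9% (24.9 to 33.1), or 8.88% and 58.5%, with 1 of 43 and 0 of 21 in neuron-like cells. S100B was found in 44.2% (43.2 to 45.2) and 67.6% (63.3 to 71.8), or 59.5% and 90.4%, with 8 of 43 and 2 of 21 in neuron-like cells. GFAP was found in 49.2% (48.2 to 50.3) and 29.3% (25.3 to 33.6), with 6 of 43 and 0 of 21 in neuron-like cells. Before thinning the order of the GFAP shares was the other way, 56.5% and 61.0%.

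**Figure D3:**
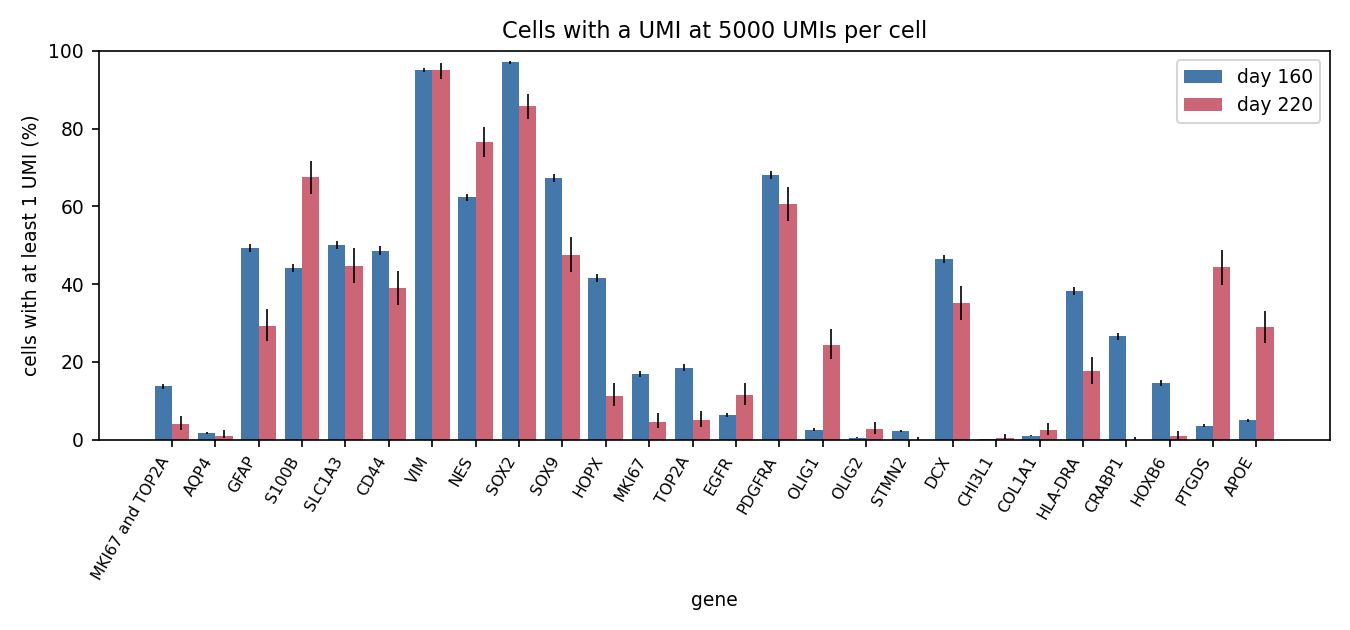
Bars are the share of kept cells, each thinned to 5000 UMIs, with at least 1 UMI of a gene (or of both MKI67 and TOP2A) in each library, and black lines are exact 95% binomial intervals for counting error. CRABP1 stands at 26.5% at day 160 and at 0 of 488 cells at day 220, and OLIG1 stands at 2.56% and 24.4%.

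The day 160 library formed 11 clusters, of which the named ones were astrocyte-like, neuronal precursor-like, cycling-like, radial glia-like, muscle-like and neuron-like. The astrocyte-like cluster 1 (2038 cells, 21.6% of kept cells) had 8 astrocyte and 6 radial glia markers, with 0 of either among its top 10 genes, so the 2 identities were not clearly apart. It was led by genes of the HLA class II antigen-presenting complex, HLA-DPA1, HLA-DRA, HLA-DRB1, HLA-DPB1 and HLA-DMA. HLA-DRA was found in 90.2% of its thinned cells, against 12.9% in cluster 3. Cluster 3 (1251 cells, 13.2%), neuronal precursor-like, was led by genes that included CRABP1, HOXB6, HOXB5 and DLX6-AS1. Clusters 5, 6 and 10 were cycling-like (1064, 644 and 231 cells), led by PCLAF and TYMS, by UBE2C and CDC20, and by TYMS and CCNE2. Cluster 7 (402 cells, radial glia-like on 3 markers) was led by RAMP1, GPC3 and NTRK2. Cluster 9 (264 cells, 2.79%), muscle-like, was led by COL1A1, TAGLN, ACTG2, C6orf15 and ACTA2. It also had progenitor genes, with SOX2 at 671 CPM and NES at 732 CPM, against 986 and 431 CPM in cluster 1. The name therefore does not make these muscle cells. The median of 32512.5 UMIs in cluster 9 was 3.23 times the library median. Its median doublet score of 0.091 was the highest of the day 160 clusters, so unmarked doublets among these cells are open. Cluster 11 (70 cells), neuron-like, was led by STMN2, NSG2 and RBFOX1. Clusters 2, 4 and 8 (1970, 1210 and 303 cells) stayed unnamed and were led by CALB2 and SCGN, by DHRS3 and ACVR2A, and by NMU and PTTG1.

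The day 220 library formed 7 clusters. Cluster 1 (154 cells, 29.7%) and cluster 4 (64 cells, 12.4%) were neuronal precursor-like, the first led by PEG10, the neuropeptide gene NPY, DLX6-AS1, NRXN3 and DLX5, the other by CHRNA1, RIC3 and GADD45G. Cluster 2 (122 cells, 23.6%), astrocyte-like on 7 markers against 5 of radial glia, was led by SPARCL1, HLA-DPA1, EDNRB, HLA-DRA and CA2. Cluster 3 (69 cells, 13.3%) stayed unnamed and was led by OLIG1, DPP6, SMOC1, CADM2 and BCAN, and OLIG1 was found in 79.1% of its thinned cells. Cluster 5 (52 cells), muscle-like, was led by COL1A1, ANKRD1, TAGLN, CCN2 and ACTA2, and also had SOX2 at 393 CPM and NES at 885 CPM. Cluster 6 (33 cells), cycling-like, was led by TOP2A and MKI67. Cluster 7 (24 cells), neuron-like on 8 neuron markers against 6 of precursors, was led by BRINP1, CALB2 and SCGN and had no UMI of STMN2. When both libraries were clustered together, 494 of the 518 day 220 cells (95.4%) formed 1 cluster with 0 day 160 cells, so cluster sizes were not compared between the libraries. The share of astrocyte-like cells at day 160 was 32.1% at resolution 0.3 and 8.21% at resolution 1, and that of precursor-like cells at day 220 was 42.1%, against 20.7% at resolution 1 and 18.1% with a mitochondrial limit of 25%. Muscle-like cells were 10.0% at day 220 and 24.7% at resolution 0.3, and 2.79% at day 160 and 6.05% with the 25% limit.

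Within the astrocyte-like class (2038 cells at day 160 and 122 at day 220) most measured genes of the FGF and ERK list and of the p53 and senescence list were at least 2-fold higher at day 220. Most of the cholesterol synthesis list were at least 2-fold lower. Of 13 FGF and ERK genes 11 were at least 2-fold higher and 0 lower, with a median log2 ratio of 2.15 and SPRY1 17.7-fold higher (15.7 to 20.1). Of 12 p53 and senescence genes 8 were higher and 0 lower, with a median of 1.40 and CDKN2A at 3.24. Of 16 cholesterol synthesis genes 12 were lower and 0 higher, with a median of -1.39, MSMO1 4.60-fold lower (4.31 to 4.90) and HMGCS1 3.11-fold lower (2.94 to 3.28). GFAP had a log2 ratio of -2.32, HOPX was 3.72-fold lower (3.53 to 3.92), S100B 3.18-fold higher (3.09 to 3.27) and APOE 7.19-fold higher (6.80 to 7.61). Extracellular matrix genes had a median of 1.26 with 8 of 12 higher, and 0.06 after centring on intron length. Neuron genes had a median of 1.46 with 5 of 9 higher and 1 lower, or 0.30 after centring, and GAD1 was 96.3-fold higher (60.9 to 162), or 5.01 in log2 after centring. Its day 160 level in this class rested on 19 UMIs. GAD1 was also 7.58-fold higher in precursor-like and 22.15-fold higher in muscle-like cells, so its higher level was not particular to astrocyte-like cells. The class had 2276 genes at least 2-fold higher and 505 lower of 9835, and 1035 and 761 after centring. Of the genes past 2-fold, 81.8% were higher, or 57.6% after centring.

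In the neuronal precursor-like class (cluster 3 at day 160, clusters 1 and 4 at day 220, 1251 and 218 cells) the 10 measured precursor genes were all at least 2-fold lower at day 220, with a median of -2.03 and DLX2 3.69-fold lower. The same list named these clusters, with 8 markers in cluster 3 of day 160 against 5 and 4 in clusters 1 and 4 of day 220. This difference is therefore not independent of how the class was chosen. The glial lists had medians above 0 in this class: the astrocyte list had a median of 1.21 with 5 of 10 higher and 0 lower, and the AC-like list 1.43 with 22 of 32 higher and 2 lower, or 1.03 and 1.26 after centring on intron length. The radial glia list had a median of 1.37 with 9 of 17 higher and 2 lower, or 0.05 after centring, and the forebrain list had -0.15 with 3 of 9 higher and 4 lower. VIM was 5.51-fold higher (5.38 to 5.65). The 2 day 220 clusters pooled here differed, with AC-like scores of -0.58 in cluster 1 and 0.29 in cluster 4, and cluster 4 had the highest median doublet score of day 220, 0.09, so doublets among its cells are open. The 5 hindbrain and spinal genes had a median of -5.76, with HOXB6 329-fold lower (160 to 820). HOXB genes themselves led cluster 3, and the unnamed cluster 2 of day 160, with 6 precursor markers, was not in the class, so the cells compared were matched neither for regional identity nor for glial genes. FGF and ERK genes had a median of 2.23 with 9 of 13 higher and 1 lower, and p53 and senescence genes 0.92 with 4 of 11 higher. The class had 2786 genes at least 2-fold higher and 511 lower of 9886, and 1277 and 919 after centring. Of the genes past 2-fold, 84.5% were higher, or 58.2% after centring. In the muscle-like class (264 and 52 cells) the 5 measured muscle genes had a median of -1.03, with 3 at least 2-fold lower and 0 higher, or -0.85 after centring. FGF and ERK genes had a lower median here than in the other 2 classes, 0.63 with 5 of 13 higher and 1 lower, as did p53 and senescence genes, 0.33 with 3 of 12 higher. TAGLN and ACTA2, genes of contractile cells, were 2.20-fold (2.14 to 2.27) and 1.60-fold (1.56 to 1.65) lower, and COL1A1 had 398 CPM and 386 CPM. The 16 cycling genes had a median of -4.33. This value depends on where the clustering placed dividing cells, since the other day 220 clusters together had 0.6 CPM of MKI67 against 387 CPM in the cycling-like cluster, and on the day 160 cluster for which doublets are open. The muscle-like class had 1936 genes at least 2-fold higher and 513 lower of 9820, and 855 and 752 after centring. Of the genes past 2-fold, 79.1% were higher, or 53.2% after centring. The cycling class, with 1939 and 33 cells, and the neuron class, with 70 and 24, were too small to compare.

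Of the 9 glioblastoma lists, 7 scored highest in clusters of the same name in the 2 libraries, and the NPC1-like and OPC-like lists did not. Several of these ranks rested on differences smaller than the half-widths over members, so not all of the matches and mismatches are settled. The AC-like list, the astrocyte-like tumour state, scored highest in the astrocyte-like cluster, at 1.24 at day 160 with GFAP, TTYH1 and FABP7 leading and at 1.15 at day 220 with SPARCL1, EDNRB and SLC1A3 leading. The MES1-like and MES2-like lists and the mesenchymal subtype scored highest in the muscle-like cluster, at 1.01, 0.48 and 1.21 at day 160 and at 0.78, 0.44 and 0.98 at day 220, with the astrocyte-like cluster next. The muscle-like clusters also had SOX2 and NES. For the MES1-like list the astrocyte-like cluster was close, at 0.84 and 0.59, with half-widths over members of 0.26 and 0.23 for the highest scores. For the MES2-like list it was close at day 220, at 0.32, with a half-width of 0.16 for the highest score. Those ranks are not settled. The NPC2-like list scored highest in the neuron-like cluster, at 1.23 and 1.31, as did the proneural subtype, at 0.46 and 0.38. For the proneural subtype cycling-like clusters came next, at 0.29 and 0.25, and the half-widths over members of its highest scores were 0.35 and 0.34. The 2 neuron-like clusters share a name but not their leading genes. These were STMN2, NSG2 and RBFOX1 at day 160 and BRINP1, CALB2 and SCGN at day 220. CALB2 and SCGN also led the unnamed cluster 2 of day 160. The only STMN2 UMI of the day 220 library lay in precursor-like cells, so the neuron-like cluster of day 220 had none. The shared name therefore does not show that the NPC2-like and proneural lists scored highest in the same kind of cell. The NPC1-like list scored highest in clusters 2 and 3 of day 160, at 0.63 in both, and in the neuron-like cluster of day 220, at 0.51. At day 160 the neuron-like cluster was close at 0.54, with a half-width over members of 0.31, so this mismatch is not settled. The OPC-like list, the oligodendrocyte-precursor-like state, was highest in the astrocyte-like cluster of day 160, at 0.42, and in the OLIG1-led cluster 3 of day 220, at 0.66. At day 160 the unnamed cluster 4 was next at 0.27, and the half-width over members of the highest score was 0.26, so that rank is not settled. The classical subtype was highest in the astrocyte-like cluster, at 0.28 and 0.20. At day 220 the OLIG1-led cluster 3 was close to it at 0.18, with half-widths over members of 0.14 and 0.09, so that rank is not settled. The percentile of the highest score of each list in each library among random lists was 99.9 or above. With a pseudocount of 1 CPM in place of 10 the highest mesenchymal subtype scores were 1.98 and 1.57, and with doublets kept the highest classical score of day 160 was 0.49. List members overlap with the markers that named the clusters, so these placements are not independent of the names.

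**Figure D4:**
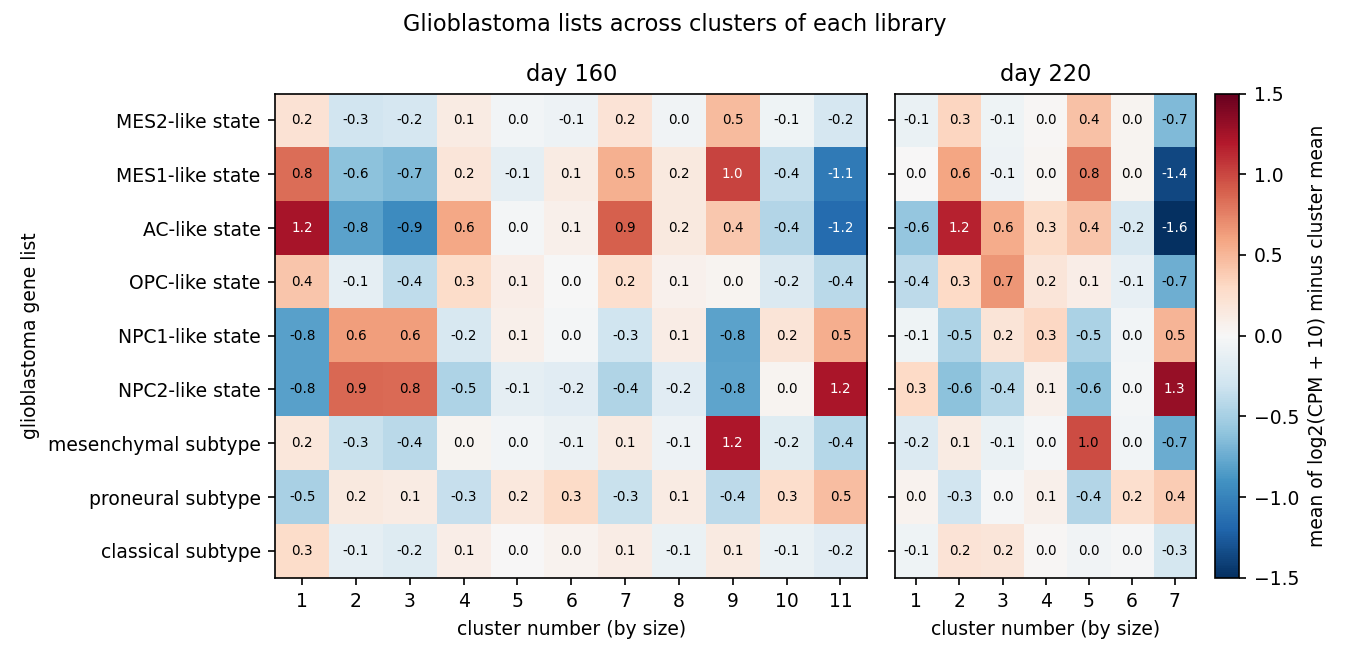
Each cell of the grid is the score of a glioblastoma list (vertical) in a cluster (horizontal, numbered by size within its library), in log2 units above or below the mean of the clusters of that library. The AC-like list reaches 1.24 in cluster 1 of day 160 and 1.15 in cluster 2 of day 220.

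Between the libraries, the NPC-like lists had medians below 0 over all kept cells, and the OPC-like and classical lists were higher before centring on intron length. The OPC-like list had a median of 0.75 with 18 of 41 members at least 2-fold higher and 2 lower, which was 0.26 with 11 higher and 5 lower after centring and -0.07 among its members with short introns. After centring the OPC-like median was still at percentile 99.7, with an interval over members of -0.02 to 0.84. The classical list had a median of 0.74 with 17 of 46 members higher and 2 lower, which was 0.03 with 7 higher and 5 lower after centring, at percentile 81.5. The NPC1-like and NPC2-like lists had medians of -0.49 (-1.08 to 0.12 over members) and -0.56 (-0.97 to 0.14), both at percentile 0.0. Of their members 16 of 45 and 16 of 48 were lower against 11 and 4 higher, and the medians were -1.35 and -1.08 among members with short introns. After centring 4 and 0 were higher and 18 and 20 lower. In astrocyte-like, muscle-like and precursor-like cells the NPC1-like median was 0.28, 0.25 and -0.91, or -0.22, 0.03 and -1.03 after centring. The NPC2-like median was -0.02, -0.19 and -1.0, or -0.41, -0.47 and -1.17 after centring. The lower levels were thus largest in the precursor-like class, whose cells were not matched. The proneural list had a median of -0.52 with 8 of 26 higher and 7 lower, or 3 higher and 10 lower after centring and a median of -1.29 among 6 members with short introns. The AC-like list stood at -0.16 with 10 of 37 higher and 7 lower, or -0.02 after centring. METTL7B, PMP2 and BCAN were 9.03-fold (8.19 to 9.97), 6.99-fold (6.59 to 7.41) and 4.15-fold (4.02 to 4.29) higher, opposite to GFAP. The MES1-like, MES2-like and mesenchymal subtype lists had medians of 0.01, 0.13 and 0.44, with 4 of 43, 4 of 42 and 6 of 22 members higher and 8, 2 and 2 lower. After centring the MES1-like median was -0.14, and 7 MES2-like members were higher. The centred MES2-like and mesenchymal subtype medians were 0.21 and 0.37, at percentiles 99.2 and 98.7, with intervals over members that included 0.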

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

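The alternatives built on intron length and the mitochondrial limit of 25% were chosen after the data were seen, and the others before. Of 449 alternative medians of 31 gene lists, 435 lay within the interval of the reported median over its members, 13 lay outside it, and the OPC-like median, whose interval excluded 0, changed sign. In all, 20 of the 449 had the opposite sign, in 9 lists. The astrocyte median ranged from -0.64 to 0.43, the radial glia median from -0.56 to 0.08, the LIF and STAT3 median from -0.74 to 0.10, the unfolded protein response median from -0.39 to 0.05, the MES1-like median from -0.14 to 0.24, the MES2-like median from -0.04 to 0.21, the AC-like median from -0.30 to 0.20 and the mesenchymal subtype median from -0.13 to 0.91, so their direction was not settled. The glutamate median, 0.00 as rounded, ranged from -0.3 to 0.1 and had no settled direction either. The FGF and ERK median ranged from 1.34 to 1.95 and the cycling median from -2.35 to -1.76. Of 2107 alternative ratios of 146 single genes, 1106 lay outside the counting interval of the reported ratio and 16 had the opposite sign, 2 of them in genes at least 2-fold apart. Of 250 alternative shares of cells with a UMI, 150 moved. Of 99 alternative glioblastoma scores 11 moved, of 49 gene counts 15, of 14 cycling shares 7 and of 32 shares of cells in a class 18. Single genes and shares were compared with counting intervals, list medians with intervals over members, and gene counts with a limit of 1.5 times. There was no replicate to give a spread between cultures. The day 220 library held 518 cells, and a gene with a UMI in 0 of its 488 thinned cells has a share of up to 0.61% of cells with a UMI at that depth, which does not limit the share at full depth. No paired analysis was possible because each time point had 1 library and no result came from a test.

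The stricter cell filter gave a cycling median of -2.35 and a midbrain, hindbrain and spinal median of -3.57. The latter was -3.26 with the mean of per-cell CPM, -3.13 with cells thinned to 5000 UMIs, -1.92 with a pseudocount of 5 CPM, and -0.08 over 17 members without an expression filter. The unfolded protein response median was -0.39 once centred on the median of all genes, which subtracts 0.14 by construction. Without an expression filter 4055 genes were at least 2-fold higher, and with 50 CPM 1008 were higher and 218 lower, since these alternatives count more and fewer genes. Without cycling-like clusters the cycling median was -2.35. For the other values in this paragraph the cause was not tested.

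Centring on intron length gave 1027 genes higher, a neuronal precursor median of -0.95 and a classical median of 0.03, and changed the sign of CALD1 to -0.43 and of SYT1 to -0.48, since it removes the trend with intron length. It gave 1035 higher and 761 lower in astrocyte-like cells, 1277 and 919 in precursor-like cells and 855 higher in muscle-like cells. Among genes with short introns 91 were higher and 243 lower of 2448, the OPC-like median changed sign to -0.07 over 9 members, and the NPC1-like, NPC2-like and proneural medians were -1.35, -1.08 and -1.29, over fewer members.

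The share of cells with both MKI67 and TOP2A at day 160 was 7.42% at 2000 UMIs, 23.86% at 10000, 16.61% unthinned, 12.62% with all barcodes, 11.94% with a mitochondrial limit of 25% and 21.77% with either gene, and at day 220 it was 1.78% at 2000 UMIs. Thinning to 10000 UMIs also left out 4682 of 9447 cells at day 160, so depth and the set of cells differed at once. Either gene in place of both raises the share by construction, and for the others the cause was not tested.

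At resolution 1 day 160 had 18 clusters, with 8.21% astrocyte-like, 24.17% cycling-like and 16.75% precursor-like cells and an AC-like score of 1.48, and day 220 had 20.66% precursor-like cells. At resolution 0.3 the values were 32.09% astrocyte-like and 2.35% muscle-like at day 160, and 29.54% astrocyte-like, 35.14% precursor-like and 24.71% muscle-like at day 220. With doublets kept they were 27.44% astrocyte-like, 22.03% cycling-like and 21.14% precursor-like at day 160, 35.5% precursor-like at day 220, and a classical score of 0.49 at day 160. With a mitochondrial limit of 25% they were 26.01% astrocyte-like, 18.24% cycling-like, 16.12% precursor-like and 6.05% muscle-like at day 160, and 18.05% precursor-like at day 220. Clustered together, on all variable genes or on those with short introns, day 220 cells were the majority in 1 cluster each time, with 95.4% and 91.51% of them in it. This gave no comparison within classes and no glioblastoma scores for day 220. For these values the cause was not tested.

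With a pseudocount of 1 CPM in place of 10, the highest MES2-like, MES1-like, AC-like, mesenchymal and classical scores at day 160 were 0.71, 1.29, 1.59, 1.98 and 0.46. At day 220 the highest MES2-like, MES1-like, AC-like and mesenchymal scores were 0.62, 1.03, 1.53 and 1.57. A smaller pseudocount widens log2 differences by construction.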

Other observations

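The test of intron counting was written before its result was seen and the other tests in this part after. At day 160, CRABP1 and HOXB6 marked cells in a precursor-like, a radial glia-like and a cycling-like cluster. At 5000 UMIs per cell CRABP1 was found in 94.3% of cells of cluster 3, 56.2% of cluster 7 and 81.2% of cluster 10, and HOXB6, a gene of posterior identity, in 68.6%, 54.2% and 39.7%. In the other clusters of day 160 HOXB6 was found in 18.6% or fewer. Clusters 3, 7 and 10 did not hold all day 160 cells with CRABP1, and some lay in other clusters. In day 220 cells HOXB6 was found in 3.92% or fewer of any cluster, the highest being the muscle-like cluster, where 48.1% had it before thinning. Between muscle-like cells of the 2 libraries HOXB6 had 17.6 CPM and 17.8 CPM, a ratio of 1.01 (0.772 to 1.31), and in precursor-like cells 286 CPM and 0.87 CPM. In astrocyte-like cells HOXB6 had 2.71 CPM and 2.24 CPM, a ratio of 0.83 (0.46 to 1.40). The precursor-like class of day 160 was cluster 3 alone, which HOXB6 itself led, so the classes do not compare on equal terms.

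OLIG1 and PTGDS were higher at day 220 within classes of cells as well, both singled out after their values were seen. In astrocyte-like cells OLIG1 was 89.4-fold higher (59.4 to 141) and PTGDS 33.5-fold higher, and in muscle-like cells they were 63.1-fold (44.8 to 91.7) and 88.5-fold higher. Cholesterol synthesis genes differed between classes, with a median of -1.39 in astrocyte-like cells, 0.42 in precursor-like cells and 0.01 in muscle-like cells. In the same order the interferon medians were -0.87, 0.33 and -0.86 and the reactive astrocyte medians -0.67, 0.70 and -0.80. These differences between classes were not tested.

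Genes with long introns were higher at day 220. A different mix of cell types is argued against, since the median log2 ratio of genes with over 300000 intron bases was at least 2.28 in each of the 3 classes compared. Fuller counting of introns in the day 220 library may account for the pattern: 96.9% of its cells had a larger share of UMIs from genes with over 100000 intron bases than the 95th percentile of day 160 cells, although a difference with time that reaches nearly every cell would give the same value. More nuclear RNA in the day 220 cells cannot be told apart from these, since the nuclear transcripts MALAT1, NEAT1 and KCNQ1OT1 had a median of 0.24 but went apart, at 0.03, 2.45 and 0.24. A biological difference between the times was not tested.

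CRABP1 was near 0 at day 220. Too few cells is argued against, since CRABP1 was found in 0.0% of 488 thinned cells at day 220 against 26.5% at day 160, and in 1.35% against 31.3% before thinning. A differentiation that is missing from the day 220 pool could give this difference, if it held the 26.5% of day 160 cells with CRABP1. It cannot be told apart from a difference with time, since no label separates the 3 differentiations.

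Fewer cells had both MKI67 and TOP2A at day 220. Depth per cell is argued against, since the share was at least 3.51 times as high at day 160 at each of 3 thinning depths, the deepest of which left out 4682 day 160 cells. Dilution by counts from introns is argued against as the whole cause, since the cycling median was -1.84 after centring on intron length. A difference in the cultures, with time or otherwise, stays open and was not tested.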
